A study of Mus musculus with 8 samples.

How the data were processed

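Kidney RNA from 8 mice was profiled by RNA sequencing. All mice had been given iron dextran, a complex used to load tissues with iron, at 0.4 mg per gram of body weight on 5 days, and were killed 3 days after the last dose, per the labels' protocols. In 4 mice, numbered 9 to 12, myeloid cells lacked ferritin heavy chain (FtH, the product of Fth1). The other 4, numbered 13 to 16, were wild-type mice that carried the floxed FtH allele. Each number was taken as a separate mouse, as the labels give 4 mice per genotype.

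The authors deposited raw counts per gene, made with bcl2fastq 2.18.0.12, STAR 2.7.7a and HTSeq 0.11.3 on the mouse genome build GRCm38.p6, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands could not be told apart. The deposited table held 56262 gene rows and 5 counter rows for reads given to no gene. The counter rows made up 29.85% to 32.2% of all entries of a library, most of them reads with more than one alignment, and were kept out of library sizes and tests. Discarding such reads lowers the counts of paralogs such as Lyz1 and Lyz2, the H2 genes, immunoglobulin genes and haemoglobin genes, whose values are therefore uncertain. Of the gene identifiers, 55227 matched GENCODE release M21 for GRCm38, without regard to the version suffix, and 1035 did not. Names and positions come from that annotation.

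Genes with enough reads were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10), which left 16982 genes. Library sizes were scaled with TMM factors. The genotypes were compared with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are FtH-deficient over wild-type, and values per genotype are CPM, reads scaled to a common library size, given as mean ± SD. Where a genotype had no read of a gene, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 reads, the ratio is given with an exact 95% counting interval. Such intervals and floors cover counting error only.

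Before the data were examined, 40 gene lists were fixed, and 37 of them had at least 3 tested members. They were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were alternatives. The genes named in the text were set by a rule written at the same time. It takes Fth1, Snca and Lyz2. It takes the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between the genotypes, leaving out genes known only by a placeholder name. It takes up to 4 members with the lowest p of each list described. Xist and Y-linked genes serve as a check of the libraries. Genes named outside this rule were chosen after their values were seen. These are Mmrn1, Tcerg1l, Gm9008, Madcam1, Cxcl13, Chil3, Plac8, Npas2, Arntl, Slc11a2, Il18, Cx3cr1, H2-Ab1, H2-K1, H2-D1, H2-Q4, B2m, Psmb8, Gpx4, Acsl4, Ftl1, Havcr1, Adgre1, Cxcl1, Gprin3, Ccser1, Alas2, AC154912.2 and the haemoglobin genes.

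The alternatives were RLE and upper quartile factors, DESeq2 1.42.0, limma-voom with and without quality weights, robust edgeR, no filter, a filter of at least 5 CPM in 4 libraries, leaving out the 20 most abundant genes, a minimum log2 fold change, leaving out each library, and an erythroid covariate. A term for sex was not run, since Xist and the Y-linked genes did not split the libraries. The steps were tested on simulated counts with the means, sizes and dispersions of these libraries. Over 16753 simulated genes, 92% of the genes changed 4-fold, 66% of those changed 2-fold, 50% of those changed 1.5-fold and only 16% of those changed 1.25-fold were recovered. Of all simulated calls, 7.44% were false.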

Results

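The kidneys of 8 iron-loaded mice were compared, 4 with FtH-deficient myeloid cells and 4 wild-type. Total gene counts were 26852265 to 31256094 in the FtH-deficient libraries and 25267410 to 40019806 in the wild-type ones. The most abundant gene took 3.37% to 4.5% of the counts of a library. The first principal component held 31.2% of the variance and separated the genotypes. Correlations of log2 CPM were 0.985 to 0.990 within a genotype and 0.978 to 0.985 between genotypes. No pair of libraries of 1 genotype agreed within sampling noise (chi-square per degree of freedom 8.28 to 30.9). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were detected in all 8 libraries and did not pass the test between genotypes. Xist, outside the tested genes, had 4 to 30 reads in each FtH-deficient library and 0 to 7 in each wild-type one, so the ranges overlapped.

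The comparison of genotypes asks how ferritin heavy chain in myeloid cells shapes the kidney's transcripts under iron load. The series title names Snca and ferroptosis. Fth1 (ENSMUSG00000024661.7, chromosome 19, 9980598 to 9985098, GRCm38), the targeted gene, was lower in FtH-deficient kidneys, at 3624 ± 136 CPM against 4529 ± 392 CPM (SD, n = 4). Its log2 fold change was -0.32 (SE 0.0735, edgeR adjusted p = 0.0441). The deletion is limited to myeloid cells, so whole kidney need not show a large fall. The call held in only 1 of the 8 fits without 1 library, that without wild-type mouse 16, and the adjusted p reached 0.138 without FtH-deficient mouse 12. Lyz2 (ENSMUSG00000069516.8, chromosome 10, 117277331 to 117282321), which encodes a lysozyme of myeloid cells and is a common site for inserting a myeloid Cre recombinase, was nearly absent in FtH-deficient kidneys, at 0.723 ± 0.345 CPM against 226 ± 39.7 CPM. Its log2 fold change was -8.26 (SE 0.217, edgeR adjusted p = 1.68e-09). The labels do not name the Cre driver. The near absence of Lyz2 coincided with FtH deficiency in all 4 mice. Differences between the groups, in this and later paragraphs, can therefore not be assigned to FtH alone.

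Snca (ENSMUSG00000025889.13, chromosome 6, 60731575 to 60829855) encodes alpha-synuclein. It had 17 to 26 reads in each FtH-deficient library, 83 in all, and 0 in each of the 4 wild-type libraries. It was thus at least 30.6-fold higher in FtH-deficient kidneys at the floor of 3 counts over the group (edgeR adjusted p = 0.000931), though its level there was only 0.709 ± 0.164 CPM. The next protein-coding gene, Mmrn1 (chromosome 6, 60924976 to 60989378), which encodes a platelet and endothelial protein, was left out by the filter on low counts. It had the same distribution, with 44 reads in the FtH-deficient libraries, 5 to 16 in each, and 0 in the wild-type ones, and passed the test without that filter (edgeR adjusted p = 0.000323). The nearest tested protein-coding genes outside this pair did not pass the test. Gprin3 had a log2 fold change of -0.12 (SE 0.181) and Ccser1 one of 0.26 (SE 0.112).

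**Figure D1:**
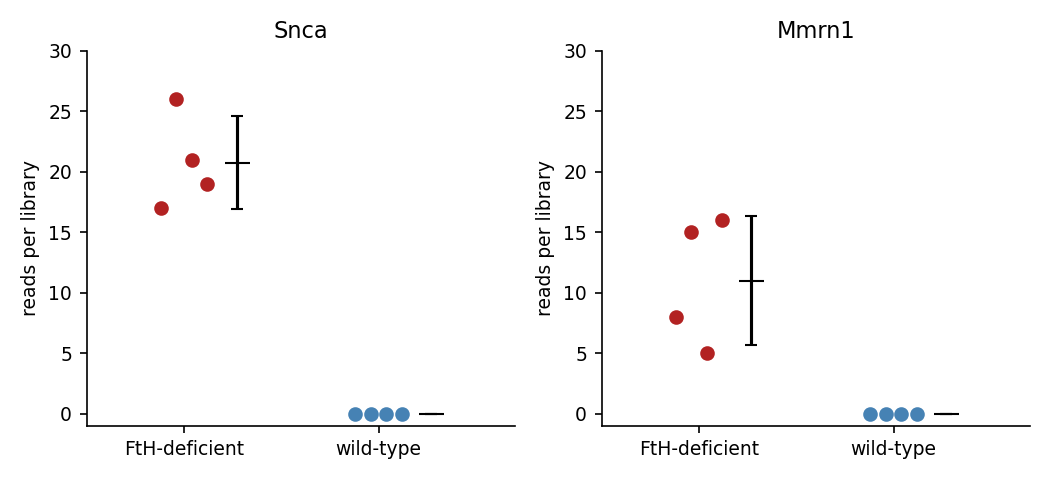
Reads of Snca and of the neighbouring gene Mmrn1 in each library (points), with the mean and SD of each genotype (n = 4). Both genes have reads in all 4 FtH-deficient libraries and 0 in all 4 wild-type libraries.

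Of 16982 genes tested, 397 passed the threshold, 205 higher and 192 lower in FtH-deficient kidneys. The genotypes did not overlap for 1700 genes, 10% of those tested, against the 2.86% that chance gives. Among called genes with a mean of at least 1 CPM, no overlap between the genotypes and a name that is not a placeholder, the largest rise was in Marco, a scavenger receptor of macrophages, with 1248 reads against 2, a ratio of 689 (95% counting interval 190 to 5700, edgeR adjusted p = 5.38e-08). Lyz1 (log2 fold change 4.58), the paralog of Lyz2, Rnf26 (3.33), Best1 (2.95), Spic (2.76), a transcription factor of red pulp and bone marrow macrophages, Slc7a11 (2.64), Slpi (2.55), Cd5l (2.39), Clec4n (2.34) and Rpl29 (2.31) followed. Reads of Lyz1 and Lyz2 can be shared, and Rnf26 overlaps other genes. Best1 lies 76 bp beyond the end of the targeted gene Fth1, on the opposite strand, so reads from the altered locus could count towards its rise. Within the same limits, the largest falls after Lyz2 were in Ighg2b (-6.07), Ighg2c (-5.00), Igha (-3.70), Igkc (-3.69), Col6a6 (-3.48), Clec3b (-3.26), Cacna2d2 (-3.26), Tmprss4 (-3.04) and Jchain (-3.01). Of these 20 genes, 6 lie on chromosome 9, namely Rnf26, Rpl29, Col6a6, Clec3b, Cacna2d2 and Tmprss4. The calls of Slpi and Ighg2c ended under limma-voom with quality weights (adjusted p = 0.0509) and under limma-voom (adjusted p = 0.0531).

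Calls were unevenly spread over the genome. Chromosome 9 held 88 of its 949 tested genes among the calls, or 9.27%, 44 higher and 44 lower, while no other autosome and not the X chromosome exceeded 2.7%. Of 14 mitochondrial genes tested, 2 were called. The odds ratio of a call on chromosome 9 was 5.20 (95% interval 4.02 to 6.68, Fisher's exact test, two-sided, p = 8.83e-30; genes are not independent replicates). In 5 Mb windows, at least 10% of the tested genes were called from 40 to 50 Mb, where 25 of 110 tested genes were called, and from 105 to 125 Mb, where 44 of 244 were. Without chromosome 9, a choice made after seeing the data, 262 genes were called.

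**Figure D2:**
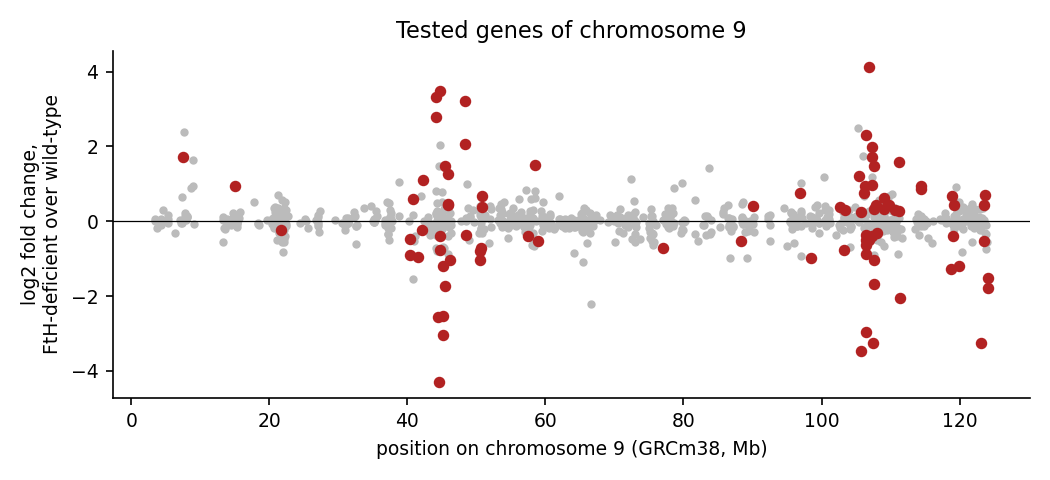
Log2 fold change, FtH-deficient over wild-type, of the 949 tested genes of chromosome 9 by position in Mb (GRCm38). Red points are the 88 called genes, which gather at 40 to 50 Mb and 105 to 125 Mb in both directions.

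Genes of iron handling moved in both directions. Hmox1, the inducible haem oxygenase, rose from 45.6 ± 5.32 to 118 ± 25.4 CPM (log2 fold change 1.37, SE 0.139, edgeR adjusted p = 0.000204). Slc40a1, the iron exporter ferroportin, rose by 0.82 on the log2 scale. Tfrc, the transferrin receptor, fell from 25.1 ± 0.746 to 11.8 ± 1.22 CPM (log2 fold change -1.09, SE 0.0833, edgeR adjusted p = 2.09e-05). Trf (-0.77, on chromosome 9), Slc11a2 (-0.35) and Fth1 also fell, so 2 members were higher and 4 lower of 32 tested, and 13 passed when adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.203). Ftl1, the light chain, had a log2 fold change of 0.18 (SE 0.080, edgeR adjusted p = 0.282). The calls of Trf and Slc11a2 ended in 2 and 6 of the 8 fits without 1 library, with adjusted p up to 0.0573 without FtH-deficient mouse 11 and up to 0.0857 without FtH-deficient mouse 12.

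Of 31 tested genes of the ferroptosis list, 3 were higher (Slc7a11, Hmox1 and Ptgs2) and 2 lower (Tfrc and Fth1), 7 passed when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.982). Slc7a11, the cystine importer, rose from 0.977 ± 0.330 to 6.20 ± 1.60 CPM (edgeR adjusted p = 0.000138). Gpx4, which reduces lipid peroxides, had a log2 fold change of 0.02 (SE 0.0772), and Acsl4 one of -0.12 (SE 0.0939). Neither passed. The call of Ptgs2 (0.82) ended in all 8 fits without 1 library, with an adjusted p up to 0.114 without FtH-deficient mouse 12. In the oxidative stress list, Slc7a11, Hmox1, Nqo1 (0.49) and Ugdh (0.48) were higher and none lower of 28 tested, and 6 passed when adjusted over the list alone. The list passed as higher with the preset correlation only (camera adjusted p = 0.000826, but adjusted p = 0.747 with an estimated correlation). The call of Ugdh ended in 3 of 8 such fits, with an adjusted p up to 0.0707 without FtH-deficient mouse 11.

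Interferon response genes were higher. Of 33 tested, 9 were higher and none lower, and 14 passed when adjusted over the list alone (camera adjusted p = 1.88e-10, but adjusted p = 0.159 with an estimated correlation). Iigp1 rose from 17.3 ± 3.51 to 47.9 ± 5.74 CPM (edgeR adjusted p = 7.65e-05). Gbp2 (1.77), Igtp (1.20) and Gbp3 (1.21) rose on the log2 scale, all 3 encoding interferon-inducible GTPases. Igtp overlaps Irgm2. Among 32 cytokine genes, the chemokines Cxcl9, Cxcl10 (1.39), Ccl2 (1.29) and Cxcl1 and the cytokine Il6 (2.68) rose and Il18 (-1.04) fell, and 14 passed when adjusted over the list alone (camera adjusted p = 0.00302, but adjusted p = 0.747 with an estimated correlation). The call of Il18, on chromosome 9, ended in 3 of 8 fits without 1 library, with an adjusted p up to 0.0705 without FtH-deficient mouse 12, and that of Cxcl1 in 6, with one up to 0.0842 without FtH-deficient mouse 9. Antigen presentation genes moved in both directions. They are given by class after their values were seen, and no difference between the classes was tested. The class II genes H2-Aa (-1.08), H2-Eb1 (-1.12), H2-Ab1 (-0.56) and Cd74 (-0.75) fell. The class I genes H2-K1 (0.40), H2-D1 (0.38), H2-Q4 (0.48) and B2m (0.36), with Tap1 (0.69) and Psmb8 (0.44) of the peptide supply, rose. The list had 6 higher and 4 lower of 20, 13 passed when adjusted over the list alone, and it did not pass (camera adjusted p = 0.203). Without 1 library the calls of B2m, H2-D1 and H2-Q4 ended in 6 of 8 fits each, that of Psmb8 in 5, that of H2-K1 in 3 and that of H2-Ab1 in 1, with adjusted p up to 0.126, for B2m without FtH-deficient mouse 11.

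Markers of macrophages and monocytes moved apart. Of 33 tested, 4 were higher, namely Marco, Cd5l, Chil3 (2.23) and Plac8 (0.44), and 8 were lower. C1qb fell from 48.0 ± 3.84 to 25.4 ± 2.48 CPM (edgeR adjusted p = 7.28e-05), as did C1qa (-0.94) and C1qc (-0.93), which encode the complement component C1q. The chemokine receptor genes Ccr2 (-1.78) and Cx3cr1 (-1.19), both on chromosome 9, also fell. Adgre1, the gene of the macrophage antigen F4/80, had a log2 fold change of -0.03 (SE 0.144). The list's median was -0.22 but its mean 0.21, and camera gave a fall (adjusted p = 0.0329, but adjusted p = 0.861 with an estimated correlation, and 0.182 without chromosome 9). In the list, 19 passed when adjusted over the list alone. Its call ended in 3 of 8 fits without 1 library, with an adjusted p up to 0.176 without wild-type mouse 16. The call of Plac8 ended in 6 and that of Chil3 in 1, with adjusted p up to 0.103 without wild-type mouse 14.

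B cell and plasma cell genes were lower. Of 15 tested, 7 fell and none rose, and 9 passed when adjusted over the list alone (camera adjusted p = 1.88e-10, but adjusted p = 0.153 with an estimated correlation). The falling genes encode immunoglobulin chains or, for Jchain, the chain that joins them. Jchain fell from 15.9 ± 3.80 to 1.98 ± 0.243 CPM (edgeR adjusted p = 2.75e-06). Fat tissue markers, a sign of tissue around the kidney, had a median log2 fold change of -1.36, with 11 of 12 tested members negative. As a list they passed as lower with the preset correlation only (camera adjusted p = 0.006, but adjusted p = 0.788 with an estimated correlation). None of the 12 was called, and 1 passed when adjusted over the list alone. Car3 was 28.0 ± 18.1 CPM against 109 ± 90.7 CPM and Cfd 15.5 ± 18.8 CPM against 66.5 ± 89.0 CPM, both highest in wild-type mouse 14 (242 and 198 CPM). The list's call ended in 1 of 8 fits without 1 library, that without FtH-deficient mouse 11 (adjusted p = 0.167). Whether such tissue adds to the falls of other genes was not tested. No erythroid gene of 16 tested passed, and 0 passed when adjusted over the list alone. The haemoglobin genes Hbb-bs and Hba-a1 had log2 fold changes of -0.53 (SE 0.473) and -0.41 (SE 0.471).

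**Figure D3:**
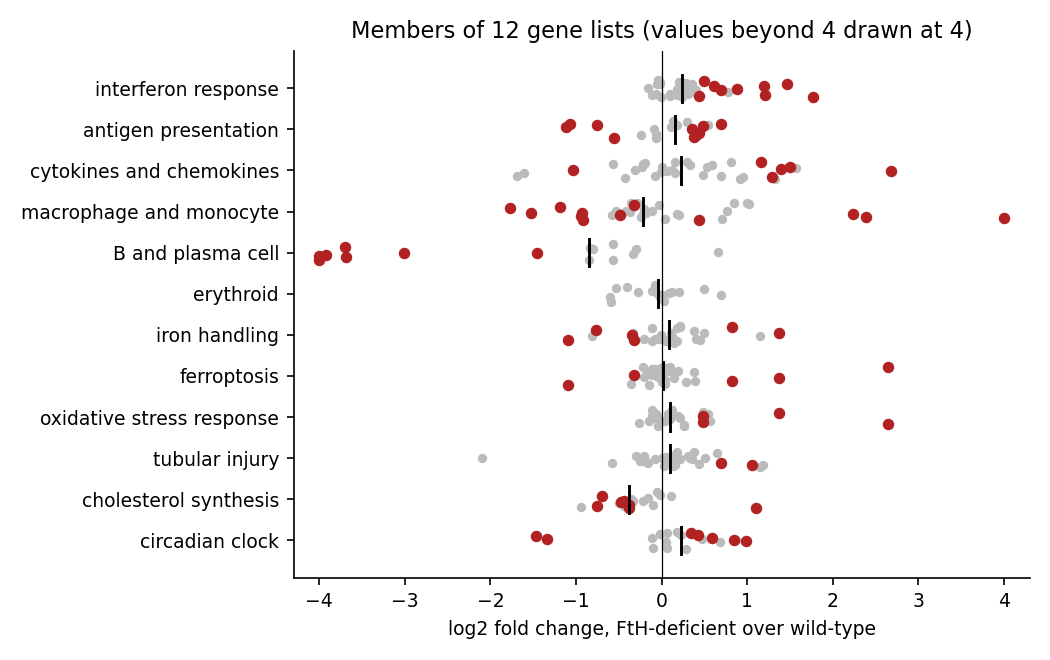
Log2 fold change, FtH-deficient over wild-type, of the tested members of 12 gene lists. Red points passed the threshold, grey points did not, black bars are medians and values beyond 4 in size (Marco, Ighg2b and Ighg2c) are drawn at 4. Macrophage markers lie on both sides of 0, while the called interferon genes all lie above it.

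Markers of the proximal tubule and of the loop and distal tubule were among the calls. Of the proximal tubule list, Lrp2 (0.30) and Slc3a1 (0.38) rose and none fell of 30 tested. When adjusted over the list alone 4 passed, 3 higher and 1 lower, and the list did not pass (camera adjusted p = 0.87). Its median log2 fold change was -0.036. The calls of Lrp2 and Slc3a1 ended in 4 and 5 of 8 fits without 1 library. Their adjusted p reached 0.0865 without wild-type mouse 14 and 0.104 without FtH-deficient mouse 12. With edgeR, none of 15 podocyte, 18 collecting duct and 19 endothelial genes passed, though 1, 3 and 5 of them had an unadjusted p under 0.05. DESeq2 and limma-voom each called 1 collecting duct gene. As lists, podocyte and endothelial genes leaned lower without passing (camera adjusted p = 0.0692 and 0.0565), but both lists passed without wild-type mouse 13. In the tubular injury list, Plaur (0.70) and C3 (1.06) rose and none fell of 34 tested. When adjusted over the list alone 9 passed, 7 higher and 2 lower. The list passed as higher with the preset correlation only (camera adjusted p = 0.0351, but adjusted p = 0.747 with an estimated correlation). The list's call ended in 5 of 8 fits without 1 library, with an adjusted p up to 0.222 without FtH-deficient mouse 12. The calls of Plaur and C3 ended in 3 each, with adjusted p up to 0.0769 and 0.0536 without that mouse. With robust edgeR, C3 and the distal tubule marker Pvalb did not pass (adjusted p = 0.122 and 0.0751). The injury markers Lcn2 (1.15, SE 0.298) and Havcr1 (0.22, SE 0.276) did not pass. In the loop and distal tubule list Umod (0.36), Slc12a1 (0.41) and Egf (0.43) rose and Pvalb (-0.99) fell, of 16 tested, and 6 passed when adjusted over the list alone. Slc12a1 lost its call in 7 of 8 fits without 1 library, Egf in 6, Pvalb in 4 and Umod in 1, with adjusted p up to 0.125, for Egf without FtH-deficient mouse 11.

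Genes of cholesterol synthesis were mostly lower. Of 20 tested, 7 fell and 1 rose, and 14 passed when adjusted over the list alone (camera adjusted p = 5.57e-08, but adjusted p = 0.153 with an estimated correlation). Msmo1 (-0.70), Mvk (-0.47) and Sqle (-0.38) fell on the log2 scale. Sc5d, on chromosome 9, rose from 22.7 ± 2.09 to 48.8 ± 2.06 CPM (edgeR adjusted p = 5.72e-06). Clock genes also differed. Dbp (0.98), Ciart (0.84), Nr1d2 (0.42) and Tef (0.34) rose and Npas2 (-1.47) and Arntl (-1.33), which encode activators of the clock, fell. Of 19 tested, 5 were higher and 2 lower, and 10 passed when adjusted over the list alone (camera adjusted p = 0.000394, but adjusted p = 0.153 with an estimated correlation). The calls of Npas2 and Arntl ended in 5 of 8 fits without 1 library, with adjusted p up to 0.102, for Arntl without FtH-deficient mouse 11. Dbp overlaps Sphk2. The time of day at death is not given in the labels.

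In all, 11 of 37 lists passed with the preset correlation and 0 with the estimated one. Other ways of splitting the 8 libraries into 4 and 4 gave up to 17 passing lists, and 13 of the 35 splits, the real one included, gave at least 11. Those other splits called at most 2 genes each. The preset adjusted p of a single list is therefore no firm sign that the list differs between the genotypes.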

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

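All tests on Snca and macrophage genes here, and those on chromosome 9 except the one without list members and the count of calls over the splits, were chosen after the results were seen. The excepted tests were written before their own values were seen. They were not part of the plan fixed before the data were examined, which did not name chromosome 9.

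Snca had no read in any wild-type library. A deletion on chromosome 6 in the wild-type mice is a candidate explanation, since Mmrn1 beside it, a signal outside the tested genes, had 44 reads in the FtH-deficient libraries and 0 in the wild-type ones, while Gprin3 and Ccser1 on either side had reads in both genotypes. A deletion of Snca and Mmrn1 is known from a C57BL/6 substrain, but the labels do not give the strain. More red blood cells in the FtH-deficient kidneys are argued against as the cause of the difference. With an intact Snca gene, the wild-type haemoglobin reads predict 140 Snca reads and the Alas2 reads 97.3. Which cells carry the Snca reads of the FtH-deficient kidneys is not settled by this, since a deletion would remove the wild-type reads of any cell. Induction of Snca by the FtH deficiency (at least 30.6-fold) cannot be told apart from another genetic difference between the groups, as both would coincide with genotype. Induction of Snca would not by itself account for the missing Mmrn1 reads.

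Calls clustered on chromosome 9. The odds ratio of a call there was 5.20, with calls in both directions. Another copy number of the chromosome is argued against by the median log2 fold change of -0.002 over its tested genes. List genes that happen to lie there are argued against too, as the odds ratio was 6.35 (95% interval 4.80 to 8.32) without all members of the fixed lists. Chance is argued against for the clustering. The 397 genes of lowest p were taken in each of the 35 splits of the 8 libraries into 4 and 4. Only the real one (1 split) had 88 on chromosome 9, and the highest of the others had 33. A share of 1 in 35 is the smallest that these splits can give. The count of calls there (88 against at most 1) decides nothing on clustering, as no other split called more than 2 genes in all. Linked genetic differences between the groups stay open and untested, since the odds ratio only restates the clustering and the counts hold no variants.

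Macrophage genes moved in both directions. Fewer macrophages alone are argued against, as 4 called members were higher. Spleen tissue in the FtH-deficient samples is not settled. The B and plasma cell list went against it, with a median log2 fold change of -0.852. The called members of that list encode immunoglobulin chains or Jchain. Of the lymph node and spleen stroma list, outside the tested genes, Madcam1 had 48 reads in the FtH-deficient libraries and 2 in the wild-type ones. Cxcl13 went the other way, with 3 and 25. Cr2, the only tested member of the stroma list, had a log2 fold change of 0.13 (SE 0.265, edgeR adjusted p = 0.862). Madcam1 passed the test without the filter on low counts (edgeR adjusted p = 0.00119), and Spic of red pulp macrophages also rose. A changed macrophage programme under FtH deficiency stays open, with 10 called members off chromosome 9. Such a change cannot be told apart from another genetic difference between the groups, since both would coincide with genotype.

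Some libraries stood far from the others of their genotype. The share of the most abundant gene was 4.05% in FtH-deficient mouse 9 against 3.47% to 3.53% in the others. The counter rows took 29.8% of entries in wild-type mouse 15 against 31.7% to 32.0%. Wild-type mouse 13 had the lowest mean log2 CPM of the extracellular matrix list (4.13 against 4.46 to 4.52), and the lowest C1qa (36.5 CPM against 41.0 to 41.5) and C1qc (29.5 CPM against 39.7 to 40.7). FtH-deficient mouse 10 had the lowest Glb1 (148 CPM against 164 to 167) and Gbp2 (30.8 CPM against 58.0 to 63.5). Cd5l was 2.08 CPM in wild-type mouse 16 against 0.655 to 0.799, and Ripk3 1.48 CPM in wild-type mouse 15 against 0.983 to 1.04. Lrp2 was 1660 CPM in FtH-deficient mouse 11 against 1520 to 1530. Chance alone gives such a gap in about 1 in 20 groups. In all 10 were found, 2 among 10 groups of library measures, 1 among 74 groups of list means and 7 among 178 groups of named genes. Together these are no more than chance alone gives. Outside the tested genes, the lncRNA AC154912.2 had 28 reads in the FtH-deficient libraries and 0 in the wild-type ones.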

How the results depend on the processing

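The chromosome 9 alternative was chosen after seeing the data. No paired analysis was possible because the genotypes share no mouse number. The sex term was not run, as Xist and the Y-linked genes did not split the libraries. The 397 called genes (205 higher, 192 lower) became 846 with DESeq2 (439 and 407), 793 without a filter (407 and 386), 144 with a log2 fold change of at least 1 (78 and 66) and 262 without chromosome 9 (139 and 123); the cause of the first 2 was not tested. Without chromosome 9, 88 calls left with it and 47 others, Fth1 among them, ended when the same p-values were adjusted anew. DESeq2 shared 391 calls with the 397. Leaving out 1 library gave 230 to 396 genes, 120 to 210 higher and 103 to 208 lower, with 230 without FtH-deficient mouse 12, 232 without 11, 238 without 9 and 260 without wild-type mouse 14. Fth1 had log2 fold changes of -0.36 to -0.26 without 1 library and -0.32 without chromosome 9 (adjusted p = 0.0536). Lyz2 passed throughout (-8.64 to -8.08 without 1 library). Snca passed in each fit that gave an adjusted p (up to 0.00508); the strict filter removed it and DESeq2 gave none. Of 86 other named calls, 58 had a value in each of 19 alternatives, and 33 of these held in all. Of the 28 without a value in at least 1, 19 held wherever there was one. None reversed.

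With an estimated correlation 0 lists passed and with fry 5; the cause was not tested. Adjusted p with an estimated correlation was 0.153 for B and plasma cell, cholesterol and circadian genes, 0.159 for interferon, 0.747 for oxidative stress, tubular injury, cytokines, fatty acid oxidation and oxidative phosphorylation, 0.788 for fat tissue and 0.861 for macrophages. With fry it was 0.138 for oxidative stress and cytokines, 0.329 for tubular injury and fatty acid oxidation, 0.51 for macrophages, 0.284 for oxidative phosphorylation, 0.618 for fat tissue and 0.045 for platelets, which passed. Endothelial genes passed as lower with the strict filter (0.0445), the erythroid covariate (0.00887) and without chromosome 9 (0.0169). Without wild-type mouse 13 the endothelial and podocyte lists both passed as lower (camera adjusted p = 5.22e-08 and 0.000271). Fat tissue did not pass with the strict filter (0.164), nor macrophages without chromosome 9 (0.182). Without 1 library, 8 to 14 lists passed, and adjusted p ranged from 0.00158 to 0.222 for tubular injury, 5.22e-08 to 0.563 for endothelium, 0.000271 to 0.67 for podocytes, 0.000271 to 0.176 for macrophages, 0.0207 to 0.504 for antigen presentation, 0.00697 to 0.405 for cell cycle, 0.00133 to 0.906 for extracellular matrix, 0.000917 to 0.935 for immediate early genes, 6.4e-05 to 0.167 for fat tissue, 0.00777 to 0.434 for collecting duct and 1.36e-05 to 0.112 for fatty acid oxidation. The filter on low counts left out Mmrn1, which passed without it (adjusted p = 0.000323).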

Other observations

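The tests of other splits on the numbers of called genes and lists were planned before their results were seen.

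Cyp4a14, a fatty acid hydroxylase, rose from 151 ± 51.1 to 459 ± 96.9 CPM (edgeR adjusted p = 0.00436, though 0.0688 with robust edgeR), and Acaa1b, on chromosome 9, rose by 0.43 on the log2 scale. The fatty acid oxidation list passed with 2 of 32 tested members called (camera adjusted p = 0.0089, but adjusted p = 0.747 with an estimated correlation). The nuclear oxidative phosphorylation list passed as lower with the preset correlation only (camera adjusted p = 6.45e-07, but adjusted p = 0.747 with an estimated correlation), with 0 of 33 members called by edgeR. In the list of the integrated stress and unfolded protein response, which did not pass (camera adjusted p = 0.212), 3 of 28 tested members were lower and 1 higher. The chaperone genes Hspa5 (-0.30) and Calr (-0.30) and Manf (-0.51), on chromosome 9, fell, and Slc7a11 rose. Calr lost its call in 7 of 8 fits without 1 library, with an adjusted p up to 0.141 without FtH-deficient mouse 12. Of the lysosome and autophagy list, 3 of 32 members were called and the list did not pass (camera adjusted p = 0.785). Its gene Glb1, on chromosome 9, rose by 0.86.

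Genes absent or nearly absent in 1 genotype were not limited to Snca, and went in both directions. Tcerg1l on chromosome 7 had 169 reads in the FtH-deficient libraries and 0 in the wild-type ones, and was at least 62.2-fold higher. Within 5 Mb, the locus itself left out, 2 of 52 tested genes were called around Lyz2, among them Lyz1, 4 of 191 around Fth1, among them Best1, and 1 of 31 around Snca.

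Other splits of the 8 libraries bear on chance. The real split called 397 genes and the highest of the others 2, so 1 of 35 splits gave as many, the smallest share possible. Chance is argued against for the number of genes. For the lists, 13 of the 35 splits gave at least the real number of 11, and the highest of the others gave 17, so chance is not excluded for the number of lists. The preset adjusted p of a single list is limited in the same way.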
